A study of Aspergillus fumigatus Af293 with 6 samples.

How the data were processed

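RNA sequencing of Aspergillus fumigatus Af293 mycelium was taken from 6 libraries, 3 from control cultures and 3 from cultures with 0.5 µM methylprednisolone. Per the labels, mRNA was enriched with oligo(dT), broken into fragments of about 200 bp and sequenced on an Illumina HiSeq instrument. The strand of the libraries, the aligner and its version are not given in the sources used here. The labels number the experiments 1 to 3 in both groups, and libraries with the same number were taken as pairs wherever the experiment enters. This was checked on the values: the deviations of same-numbered libraries from their group means correlated across genes with 0.65, 0.78 and 0.44. For libraries with different numbers the correlation lay between -0.64 and 0.34, highest for control 1 with treated library 3. Treated library 1 differed less from control 3 (SD of log2 differences 0.29) than from control 1 (0.32). The values thus pair experiment 2 most clearly. Deviations from a group mean depend on each other, so experiment 2 also shapes the correlations of experiments 1 and 3. These are no separate checks of the pairing.

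The authors deposited, for each library, the count of uniquely mapped reads per coding sequence, with genes without reads left out. The deposited RPKM values were made by the authors by dividing the reads by the coding length in kilobases and by the total of unique reads in M (mega), and recomputing them from the counts gave the same values. The authors also deposited a table that pools each group with a correction for total reads. In that deposited table the expression signal of a gene is the sum over the group of RPKM times coding length, which scales each group to 3e+09, or 237 times the control reads and 231 times the treated reads. The authors' group RPKM is the mean of the 3 libraries, with 0 replaced by 0.001, and the deposited log2 ratio is that of treated over control RPKM. The authors' P-value and FDR were used as deposited, and their test is not given in the sources used here. The calls used are those with an FDR of at most 0.001 and at least 2-fold.

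Gene names and annotations were taken from an annotation table of assembly ASM265v1 by matching coordinates. Of 9030 genes, 8989 were matched: 3457 by the same span, 4191 by overlap and the same protein, and 1341 by an overlap of at least 90%. There were 41 unmatched genes, and 32 genes shared a locus tag with another. Coordinates are those of coding sequences. No genome sequence was used here, so GC content was not examined.

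Counts were analysed in R 4.3.3. Genes with low counts were removed by filterByExpr of edgeR 4.0.16, which left 6883, and libraries were scaled by TMM. Treated and control libraries were compared by edgeR's quasi-likelihood F-test, two-sided, without a block, with Benjamini-Hochberg adjustment at 0.05. Differences between experiments were tested by the experiment term, with 2 degrees of freedom, of the edgeR fit with group and experiment. Of 40 gene lists, 30 had at least 5 tested members and were tested by camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 30 lists. These tests, the lists, the first set of alternative settings and the rule for named genes were fixed before the data were examined. CPM per group are reads over the library total, without TMM, given as mean ± SD with n = 3, while log2 differences are TMM-scaled.

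The rule named genes past the threshold with a mean of at least 5 CPM (TMM-scaled) in either group and the same direction in all 3 experiments. As there were none, it named the 8 genes per direction with the smallest p under the same conditions. It added up to 4 members of each described list with the smallest p, the 6 genes per direction with the largest ratios among the authors' calls at a pooled RPKM of at least 5, and the sterol 14-alpha demethylases, HMG-CoA reductases and genes with steroid enzyme names. Which lists to describe, and the genes given for differences between experiments, were chosen after the values were seen. The transcription factor gene AFUA_1G01590 was placed among the conidial genes by a wrong locus tag, and the list was kept as fixed. The list was also tested without it.

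The first set of alternative settings was DESeq2 1.42.0, limma voom, other scalings and filters, log2 RPKM with pseudocounts of 1 and 0.1, the experiment as a block, other list tests and leaving out each library. Further alternatives, chosen after the data were seen, were DESeq2 with the block, leaving out experiment 2, pairwise contrasts of experiments, an estimated correlation under the other settings, the conidial list without AFUA_1G01590, and a z test and an exact binomial test on pooled reads. The tests were tested on simulated data with the dispersions of these libraries and 100 genes changed at each size. Genes were drawn independently of each other, so the correlation of list members was not simulated. Without a block, 2% of 2-fold and 69% of 4-fold changes were recovered when experiments differed as in the data. With the block these shares were 82% and 100%, with 9 false calls among 6883 genes. The depth of 4.05 to 4.46 M reads limits what can be seen of genes with few reads. A count of 0 in a group allows up to 3 reads. Intervals cover counting error only, and ratios against such a floor of 3 reads take the reads of the other group as exact. Figures were drawn with matplotlib 3.10.9.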

Results

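Aspergillus fumigatus is a filamentous mould that grows from airborne spores and can infect people whose immunity is suppressed, for example by glucocorticoids. Here the strain Af293 was grown from spores in 100 mL of liquid medium in 500 mL flasks for 8 h at 37 °C and 200 rpm. The medium either contained 0.5 µM methylprednisolone, a synthetic glucocorticoid, or did not. Messenger RNA of the mycelium was sequenced in 3 experiments, each with 1 control and 1 treated culture, which gives 3 libraries per group and 6 in all. The control libraries held 4.19, 4.31 and 4.15 M (mega) uniquely mapped reads and the treated ones 4.46, 4.05 and 4.46 M, for experiments 1, 2 and 3. Reads were counted over coding sequences, and 8166 to 8471 genes had at least 1 read in a library. The gene for translation elongation factor EF-1 alpha (tef1) took 2.42% to 3.73% of the reads. The questions were which genes differed between treated and untreated mycelium, and how the 3 experiments differed from each other, which sets the background for the first.

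Without a block, no gene was called changed by methylprednisolone, and with the experiment as a block 1 (edgeR) or 3 (DESeq2) genes were. Of 6883 genes tested, 0 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test of 3 treated against 3 control libraries. At an unadjusted p under 0.05 there were 30 genes, and 294 with the experiment as a block, against 344 expected with no effect. The test without the block counts differences between experiments as error, so its 30 is no measure of how few genes differ. In simulated data it recovered 2% of 2-fold changes when experiments differed as in the data, against 82% with the block. Its 0 calls therefore do not show that 2-fold changes are absent. DESeq2 and limma voom also called 0 genes, with 16 and 24 at an unadjusted p under 0.05, and 96 in DESeq2 with the block. Libraries were taken as pairs by experiment number, and with the experiment as a block edgeR called 1 gene. This was AFUA_2G00210, a gene for a conserved protein of unnamed function on chromosome 2 (coding sequence 42726 to 44001). It was higher in the treated library of all 3 experiments, by 1.13 on the log2 scale (SE 0.15, adjusted p = 0.0128 in edgeR with the block). Its reads were 41, 195 and 349 in control experiments 1, 2 and 3 and 124, 315 and 776 in the treated ones. It also differed between the experiments, by 1.99 between experiments 2 and 1 and by 2.97 between experiments 3 and 1. Without the block its log2 difference was 1.07 (SE 0.83) with an adjusted p of 1.00. DESeq2 with the block called 3 genes: AFUA_2G00210, a short chain dehydrogenase gene (AFUA_3G00180, log2 1.04, adjusted p = 0.0299) and an AN1 zinc finger protein gene (AFUA_4G04280, log2 1.00, adjusted p = 0.0378). These 2 further genes were named after their values were seen. In edgeR with the block their adjusted p was 0.158 and 0.200.

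The genes with the smallest p under the fixed naming rule did not pass the test and are given as values. Among those with more reads in the treated libraries, the endoglucanase gene eglD (AFUA_8G06830, chromosome 8, 1672440 to 1673489) was at 23.9 ± 4.54 CPM in controls and 38.1 ± 7.67 CPM with methylprednisolone (SD, n = 3). Its log2 difference was 0.78 (SE 0.26). A further endoglucanase gene, AFUA_2G14540, was at 30.3 ± 1.60 and 43.5 ± 8.70 CPM. The conidial hydrophobin gene rodA (AFUA_5G09580), whose product coats the spore surface, was at 2.63 ± 1.68 and 6.31 ± 1.61 CPM. An L-asparaginase gene (AFUA_1G02780) was at 4.51 ± 0.47 and 6.78 ± 1.38 CPM, and an MFS transporter gene (AFUA_5G06290) at 3.56 ± 0.44 and 5.83 ± 1.16 CPM. Of the genes with fewer reads, the DnaJ domain protein gene dph4 (AFUA_4G09100) was at 12.6 ± 2.13 CPM in controls and 7.35 ± 1.32 CPM with methylprednisolone. A ubiquitin-conjugating enzyme gene (AFUA_1G15570) was at 20.7 ± 4.21 and 13.2 ± 3.31 CPM. The uncharacterised gene AFUA_6G10840 was at 18.3 ± 2.10 and 10.5 ± 1.61 CPM, with a log2 difference of -0.71 (SE 0.21). Adjusted p was 1.00 for each of these in edgeR without the block and at least 0.54 with it.

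Genes of sterol synthesis and steroid conversion were examined because the drug is a steroid. None of the 27 tested ergosterol genes and none of the 16 tested steroid and sterol handling genes passed the test, also when adjusted over the list alone. As lists they had an adjusted p of 0.461 and 0.602 in limma camera. Cyp51A and Cyp51B are the sterol 14-alpha demethylases that azole antifungals inhibit. The gene cyp51A was at 596 ± 417 CPM in controls and 513 ± 329 CPM with methylprednisolone (SD, n = 3), and cyp51B at 570 ± 359 and 426 ± 172 CPM. HMG-CoA reductase catalyses the committed step of the mevalonate pathway, which feeds sterol synthesis. Its gene hmg1 was at 169 ± 55.9 and 136 ± 32.4 CPM, while hmg2 had 1 read in all 6 libraries. With the experiment as a block the log2 differences of cyp51A, cyp51B and hmg1 were -0.16 (SE 0.16), -0.24 (SE 0.16) and -0.20 (SE 0.13), with an adjusted p of 0.997 for each in edgeR. Among the genes annotated with steroid enzyme names, a 3-beta hydroxysteroid dehydrogenase/isomerase gene (AFUA_1G06450) had 45, 75 and 65 reads in controls and 67, 112 and 96 with methylprednisolone. Its log2 difference was 0.64 (SE 0.35), with the same direction in all 3 experiments and an adjusted p of 0.844 in edgeR with the block. A 3-oxo-5-alpha-steroid 4-dehydrogenase gene (AFUA_4G07350) had a log2 difference of -0.35 (SE 0.30), a 3-ketosteroid reductase gene (AFUA_4G11500) of 0.05 (SE 0.17) and a 3-ketosteroid-delta-1-dehydrogenase gene (AFUA_5G13580) of 0.51 (SE 0.46). The extracellular 3-ketosteroid 1-dehydrogenase gene helE of the helvolic acid cluster had 5 reads in all. AFUA_5G07490 and psoF, annotated as steroid monooxygenase genes, had 16 each, and psoF belongs to the fumagillin and pseurotin clusters.

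Of 30 gene lists with at least 5 tested members, 3 were called higher with methylprednisolone by limma camera with a preset correlation of 0.01. Cytosolic ribosomal protein genes had a median log2 difference of 0.23, with 80 of 84 members above 0 (adjusted p = 1.2e-09). Genes of the respiratory chain and ATP synthase had a median of 0.11, with 55 of 61 above 0 (adjusted p = 1.4e-04). Genes of tRNA synthetases and translation factors had a median of 0.10, with 73 of 84 above 0 (adjusted p = 0.0013). None of these calls held in limma camera with an estimated correlation (adjusted p = 0.993 for all 3 lists). That correlation was 0.89, 0.39 and 0.54 for the ribosomal, respiratory and translation factor lists, against the preset 0.01. The preset p-values thus treat list members as nearly independent. The estimated correlation also gave no call for ribosome biogenesis between experiments 2 and 1 (adjusted p = 0.553), where 70 of 71 members passed. Its lack of a call therefore tells little here. No member of the 3 lists passed the test over all genes or adjusted over the list alone. Examples are the 40S ribosomal protein S27 gene (AFUA_3G06640, log2 0.36, SE 0.28), the 60S ribosomal protein L22 gene (AFUA_3G12300, log2 0.38, SE 0.30) and an ATP synthase subunit gene (AFUA_2G05510, log2 0.35, SE 0.25). The difference did not have the same sign in all experiments. The median over the ribosomal protein genes was 0.31 in experiment 1, 0.48 in experiment 2 and -0.12 in experiment 3. For the respiratory genes it was 0.25, 0.12 and -0.06, and for the translation factor genes 0.28, 0.12 and -0.06. The median coding length was 543 bases in the ribosomal, 594 in the respiratory and 1716 in the translation factor list. A trend of the differences with coding length was examined for the ribosomal list only. Leaving out control 1 or treated library 2, in fits without the block, ended these calls. Without control 1 the ribosomal list had a median of 0.07 and an adjusted p of 0.771. Without treated library 2 it had a median of -0.06 and an adjusted p of 0.197. Such a fit leaves the other library of that experiment unpaired, so differences between experiments enter the comparison. The ribosomal list's median log2 CPM was lowest in control 1 and highest in treated library 2 among the 6 libraries. Without both libraries of experiment 2, a choice made after the data were seen, its median was 0.06 and its adjusted p 0.0708. Without control 1 and without treated library 2 the respiratory list had an adjusted p of 0.890 and 0.0893, and the translation factor list a median of -0.08 in both cases, with an adjusted p of 0.0574 and 0.638. With the experiment as a block, limma camera at the preset correlation also called allergen genes (median 0.16, adjusted p = 0.00909). It likewise called backbone enzymes of secondary metabolism (median 0.21, adjusted p = 0.0438). Unlike the lists above, their medians were above 0 in all 3 experiments. For experiments 1, 2 and 3 they were 0.06, 0.18 and 0.35 for allergens and 0.29, 0.21 and 0.26 for backbone enzymes. Without the block their adjusted p was 0.0525 and 0.0674 in limma camera, and their estimated correlation 0.23 and 0.005. With an estimated correlation and the block no list was called.

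**Figure D1:**
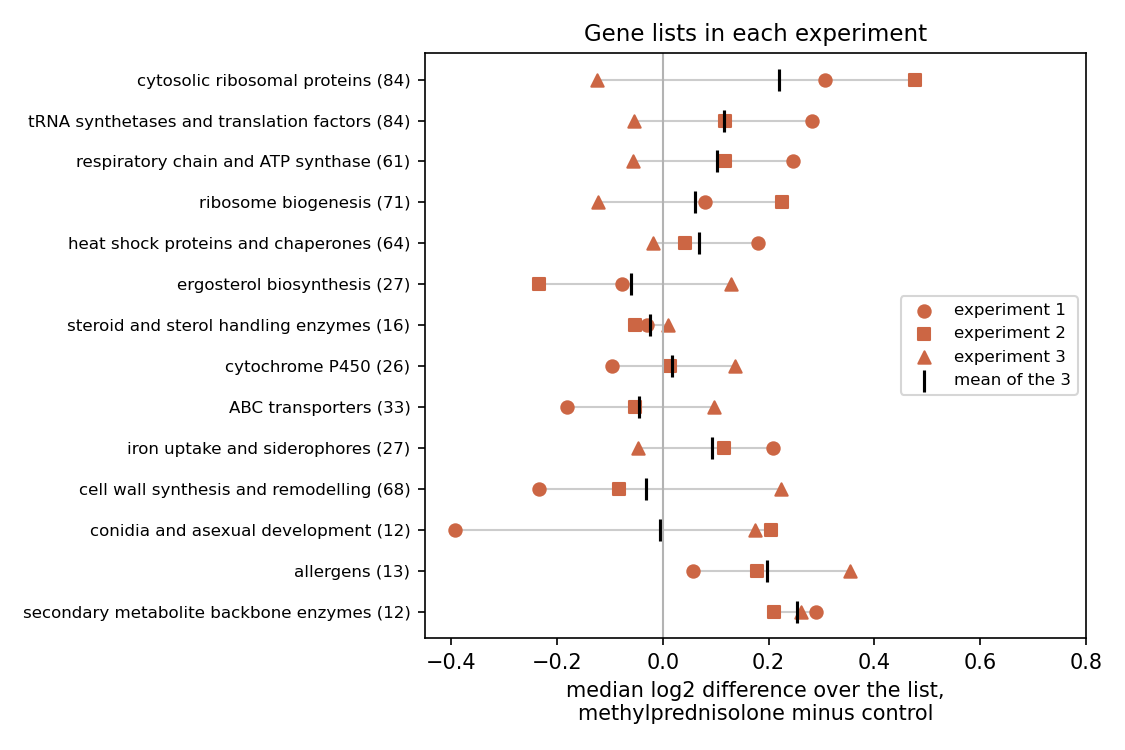
Median log2 difference between the treated and the control library of each experiment (horizontal axis) for 14 gene lists, with the number of tested genes in brackets. Each symbol is 1 experiment, the black bar is the mean of the 3 and the grey line spans them. The cytosolic ribosomal protein genes lie at 0.31, 0.48 and -0.12.

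The other 27 lists were not called in limma camera at the preset correlation without the block. Their medians ran from -0.09 to 0.18 and their adjusted p from 0.0525 to 0.978. These lists include drug and nutrient transporters, cell wall genes, chaperones and secreted enzymes. Among 33 ABC transporter genes the multidrug transporter gene abcB had 138, 70 and 65 reads in controls and 82, 52 and 35 with methylprednisolone (log2 -0.62, SE 0.36). Among 68 cell wall genes the glucanosyltransferase gene bgt1 had a log2 difference of 0.30 (SE 0.18). Among 64 chaperone genes the small heat shock protein gene AFUA_3G14540 was at 678 ± 180 and 884 ± 480 CPM (SD, n = 3). Among 27 iron uptake genes the siderophore synthetase gene sidC was at 134 ± 6.15 and 140 ± 10.6 CPM. Of the 12 tested genes of conidia and asexual development, with a list adjusted p of 0.263 in limma camera (0.569 without the misplaced gene AFUA_1G01590, where the median went from 0.01 to -0.06), the regulators abaA and wetA had log2 differences of 0.57 (SE 0.48) and -0.41 (SE 0.35). With the experiment as a block, 5 members of 4 lists passed when adjusted over the list alone, and 0 of them over all genes. They were named after their values were seen. A glutathione S-transferase gene (AFUA_2G00590, log2 1.01, SE 0.20, list adjusted p = 0.00613) and a thioredoxin gene (AFUA_5G13640, log2 0.65, SE 0.17, list adjusted p = 0.0258) belong to oxidative stress defence. The others were an MFS multidrug transporter gene (AFUA_5G02700, log2 0.67, list adjusted p = 0.00880), the DnaJ domain protein gene AFUA_5G07340 (log2 0.66, list adjusted p = 0.0176) and a sphinganine-1-phosphate aldolase gene (AFUA_4G10470, log2 -0.68, list adjusted p = 0.0318).

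The direction of difference between treated and control libraries was the same in all 3 experiments for 1599 of 6883 genes (23.2%), against 25% by chance. Across 5316 genes with a mean of at least 50 reads, which are not independent replicates, the log2 differences of experiments 1 and 2 had a Pearson correlation of 0.29. It was -0.11 between experiments 1 and 3 and -0.23 between experiments 2 and 3. The log2 differences also followed coding length, with a Spearman correlation of -0.23, -0.22 and 0.27 in experiments 1, 2 and 3. Whether this trend accounts for the correlations between experiments was not tested. At least 2-fold differences were seen in 66, 68 and 12 of these genes in experiments 1, 2 and 3.

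The 3 experiments differed from each other in many more genes than the groups did. The numbers of list genes given as higher or lower here are those past an adjusted p of 0.05 in edgeR. Of 71 ribosome biogenesis genes, 70 were higher in experiment 2 than in experiment 1 and 67 higher than in experiment 3. Of 27 iron uptake genes, 14 were lower in experiment 2 than in 1 and 16 lower than in 3, with 1 higher in each case. Of 27 ergosterol genes, 13 were lower and 3 higher than in experiment 1, and 10 lower and 5 higher than in experiment 3. In limma camera these list differences passed at the preset correlation and none with an estimated one (adjusted p = 0.553 for each of the 3 lists against experiment 1, and against experiment 3 adjusted p = 0.796 for ribosome biogenesis and iron uptake and 0.887 for ergosterol synthesis). The experiment term of the fit passed an adjusted p of 0.05 in edgeR for 2119 of 6883 genes (30.8%). Experiments 2 and 1 differed in 2143 genes, of which 1043 were higher and 1100 lower in experiment 2. Experiments 3 and 2 differed in 1602 genes and experiments 3 and 1 in 169. DESeq2 gave 1385 genes for the experiment term. Leaving out control 1, treated library 1 or treated library 2 gave 761, 979 and 1291 genes, and 340 genes passed without experiment 2. On the first principal component, with 64.6% of the variance, the libraries of experiment 2 lay at 24.9 and 44.1 and the others between -26.5 and -9.8.

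**Figure D2:**
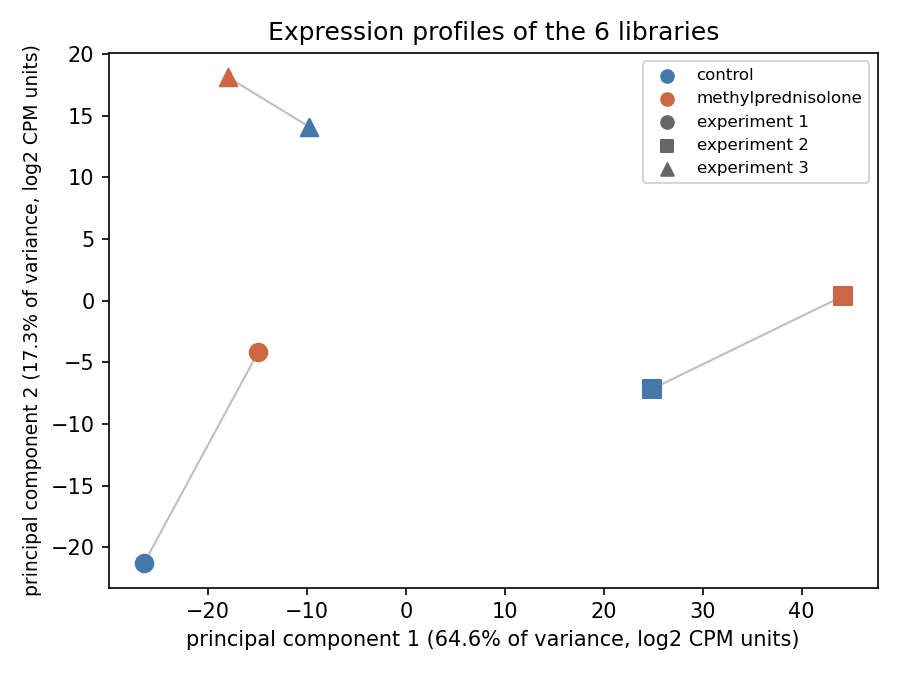
First and second principal components of log2 CPM for the 6 libraries, in log2 CPM units, with 64.6% and 17.3% of the variance. Colour marks the group (blue control, red methylprednisolone) and shape the experiment, and a grey line joins the control and treated library of 1 experiment. The libraries of experiment 2 lie at 24.9 and 44.1 on the first axis, apart from the other 4.

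All differences in this paragraph are edgeR log2 values with adjusted p. The ribosome biogenesis genes had a median difference of 1.17 between experiments 2 and 1. The nucleolar ATPase gene AFUA_1G05310 had 678, 1614 and 737 reads in control experiments 1, 2 and 3 and 757, 1707 and 764 in the treated ones. It was higher in experiment 2 than in 1 by 1.48 (adjusted p = 3.0e-05). Of 84 cytosolic ribosomal protein genes, 66 were higher in experiment 2 than in 1, with a median of 0.69. Between experiments 2 and 1 the value was -2.16 for both cyp51A and the sterol delta 5,6-desaturase gene erg3 (AFUA_2G00320), each with an adjusted p of 2.0e-05, and -1.81 for the C-14 sterol reductase gene erg24 (adjusted p = 2.6e-05). Reads of cyp51A were 4336, 887 and 2268 in the controls and 3447, 583 and 2773 in the treated libraries. The gene of the ornithine oxygenase SidA, which opens siderophore synthesis, differed by -1.79 (adjusted p = 5.8e-05), and the siderophore acetylase gene sidF by -2.68, both lower in experiment 2 (adjusted p = 0.0018). The gliotoxin cluster P450 gene gliF differed by -3.12 (adjusted p = 7.4e-05). Of 64 chaperone genes, 25 were higher and 6 lower in experiment 2 than in 1. The gene hsp78 was higher in experiments 2 and 3 than in 1, by 1.77 and 1.83 (adjusted p = 1.0e-04 and 8.2e-04), and had 565 reads in control 1 against 1543 to 3478 in the other 5 libraries. The alternative oxidase gene aox was higher in experiments 2 and 3 by 1.61 and 1.68 (adjusted p = 5.0e-05 and 1.7e-04). For experiment 2 against 1 the ribosomal protein and chaperone lists also passed at the preset correlation only, with an adjusted p of 0.553 and 0.555 with an estimated correlation.

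The authors' deposited table compares the pooled treated with the pooled control reads. It marks every one of 9030 genes, 3138 as up and 5892 as down. By the authors' deposited table, an FDR of at most 0.001 held for 8076 genes (89.4%), and 902 of these had a ratio of at least 2-fold, 400 up and 502 down. The 902 genes had a median of 3 reads over the 6 libraries, and 458 of them (50.8%) had 0 reads in one group. The count filter of the replicate-based test left out 882, and 0 of the other 20 passed that test in edgeR, 7 of them at an unadjusted p under 0.05. With the experiment as a block 1 of them passed, AFUA_2G00210. Of the 902 genes, 315 had reads in each of the 3 experiments, and 194 of these had the direction of the pooled ratio in all 3. They were selected on that ratio, so the count is no test of it. Of the called genes with a pooled RPKM of at least 5, the authors' deposited table gives the highest ratio for a Con-10 family conidiation gene (AFUA_5G03830, log2 ratio 2.19), which had 6 control and 29 treated reads. It gives 1.33 for AFUA_8G07050, 1.26 for rodA and 1.01 for AFUA_2G00210. Among the same called genes with a pooled RPKM of at least 5, the lowest ratios in the authors' deposited table were those of an opsin gene (AFUA_7G01430, log2 ratio -1.14), the small uncharacterised gene AFUA_6G08060 (-1.14) and lreA (-1.12), the gene of a GATA factor of the blue-light receptor family. The opsin gene had 160, 19 and 37 control reads and 47, 10 and 46 treated reads. The gene lreA had 563, 377 and 129 control reads and 124, 258 and 111 treated reads, and a log2 difference of -0.97 (SE 0.54) in edgeR, with -2.13, -0.34 and -0.28 in the 3 experiments.

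**Figure D3:**
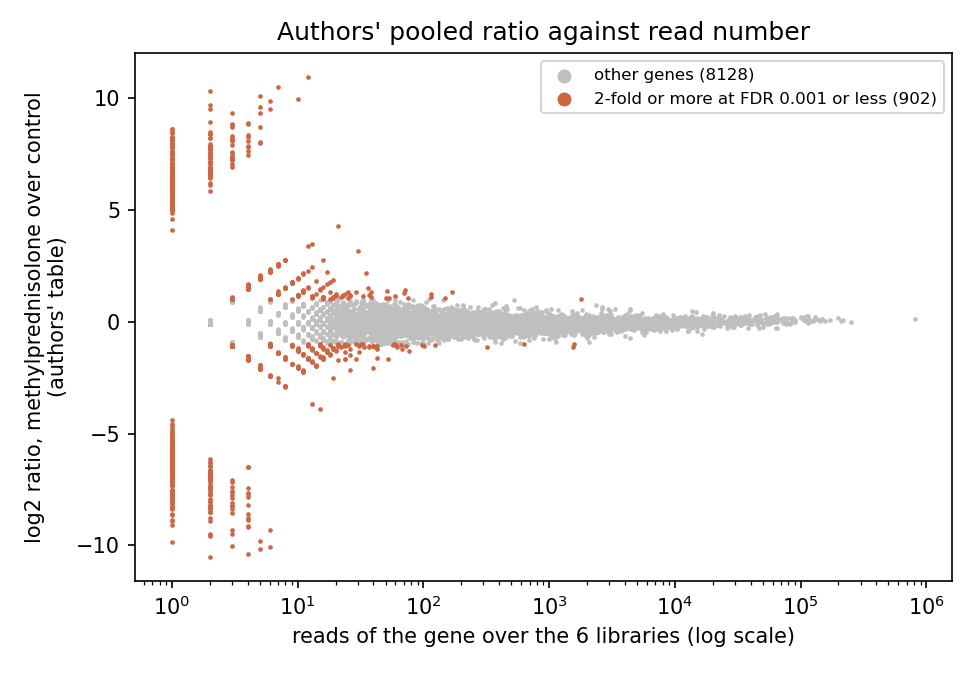
Log2 ratio of methylprednisolone over control in the authors' deposited table (vertical axis) against the reads of each gene summed over the 6 libraries (horizontal axis, log scale). Each point is 1 gene, and the 902 genes with at least 2-fold at an FDR of at most 0.001 are in red. Their median read number is 3, and genes without reads in a group carry the authors' replacement value of 0.001 RPKM there.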

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

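All tests in this part except the planned comparison of treated with control libraries were chosen after the result was seen.

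The hydrophobin gene rodC (AFUA_8G07060, chromosome 8, 1729388 to 1729956) lay below the count filter and had 12 reads in the treated libraries (7, 3 and 2) and 0 in the controls. With the controls set at 3 reads over the group, the ratio is 3.90-fold. A gene for a hypothetical protein on chromosome 6 (659721 to 661612) had 10 treated reads (4, 5 and 1) and 0 control reads, a ratio of 3.25-fold on the same setting. These ratios take the treated reads as exact, so they are not lower bounds. Both drew attention because they have reads in all 3 treated libraries and in no control. Among 2147 genes below the filter, 2 had at least 8 reads in the treated group alone and 0 in the control group alone, a minimum chosen after the values were seen. This rule leaves out genes with few control reads. Below the filter, AFUA_1G00280 had 0, 0 and 1 control reads and 4, 8 and 8 treated reads. The MFS peptide transporter gene AFUA_4G00830 had 0, 1 and 2 control reads and 6, 12 and 9 treated reads. The exact binomial test on pooled reads called both, but it leaves out differences between libraries.

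The 7 hydrophobin, Con-10 and Con-6 genes together had 17, 6 and 24 control reads and 47, 45 and 50 treated reads, a ratio of 2.92. The set holds rodA, rodC and AFUA_5G03830, whose values had been seen before it was formed, and rodA alone had 33 of the control and 81 of the treated reads. The Con-10 gene AFUA_5G03830 had 6 and 29, rodE 4 and 15, rodC 0 and 12, rodB 0 and 2, conJ 3 and 2 and the Con-6 gene 1 and 1. The reads of rodB, conJ and the Con-6 gene are too few to tell whether the whole family shares the difference. Without rodA and rodC the ratio was 3.35 (14 against 49 reads), most of it from AFUA_5G03830. A larger share of conidia in the treated cultures may account for this, and 5 other conidial genes under 1 CPM had a ratio of 1.45 (10 against 15 reads, 95% interval 0.615 to 3.64), which leaves it open. The ratio of these 5 genes was 2.19, 5.33 and 0.465 in experiments 1, 2 and 3. More abundant sets gave 0.989 for 7 pigment and spore catalase genes and 0.924 for 15 other conidial genes. The baseline of these sets would hide a small share, and the set of 5 was chosen after both were seen. The 5 genes are abr1, abr2, ayg1, arp1 and arp2, which also belong to the 7, so these ratios are not separate evidence. An effect of methylprednisolone also stays open: the exact permutation p was 0.1, two-sided, the smallest that 3 against 3 libraries allow. The set was formed after rodA, rodC and AFUA_5G03830 were seen to be higher, so this p is no support for an effect. It also ignores the pairing by experiment. The ratio of the 7 genes was 2.60, 7.99 and 1.94 in experiments 1, 2 and 3, under the same selection.

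By the authors' deposited table, 2-fold and an FDR of 0.001 were passed by 902 genes, while 0 passed in edgeR without the block. At an unadjusted p under 0.05 edgeR had 30 genes, and 294 with the block. DESeq2 and limma voom without the block also had 0 past the threshold. With the block 1 gene passed in edgeR and 3 in DESeq2. A Poisson z test on the deposited values, which exceed the reads 237 and 231 times, gave p within 20% of the deposited p for all of 1084 genes with p between 1e-04 and 1 and reads in both groups. Genes with a smaller p were not compared. The z test rebuilt the same 902 calls. This adds little, since at this scale even genes with 1 read over the 6 libraries were called, for example AFUA_1G00170. A candidate explanation is this scaling: the same z test on the values divided back to the number of reads gave 12 calls, and an exact binomial test on the reads gave 8. Differences between libraries of an experiment, which a pooled test leaves out, stay open as a source of the 8, since the 3 other splits that part every experiment gave 26, 3 and 16 calls in the exact test. No biological explanation of the difference between the tests was tested.

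Ribosomal protein genes had higher medians with methylprednisolone in experiments 1 and 2 (0.31 and 0.48) and not in experiment 3 (-0.12). For experiments 1 and 2 a trend with coding length is argued against as the whole cause. The lower of both medians was 0.27 after its removal, beyond the spread over members (median absolute deviation 0.135 and 0.111 in experiments 1 and 2). Members are correlated, so this spread is no error of the median. In experiment 3 the median was -0.07 after removal, within the spread of 0.075, so its negative sign may follow the trend. Differences between flasks may account for the higher medians in experiments 1 and 2. The list's median log2 CPM ranged over 0.61 among the 3 controls. That range also holds differences between experiments, which pairing removes, so this stays open. An effect of methylprednisolone stays open too, with an exact sign-flip p of 0.5 where 0.25 is the smallest possible.

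The 6 libraries form 10 splits, too few for a share under 0.05. Any split gives at least the real 0 genes in edgeR, so the 10 splits show nothing about that count. The highest other was 0, with 30 genes at an unadjusted p under 0.05 in the real split and 0 genes past the threshold in DESeq2 and limma voom. All 10 gave at least the real 3 lists, with a highest other of 16. The 3 other splits that part every experiment gave 6, 3 and 12 lists. The splits that keep 2 experiments together gave 9 to 16 lists, and up to 1489 genes at an unadjusted p under 0.05, which points to the structure of the experiments.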

How the results depend on the processing

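The alternatives DESeq2 with the block, an estimated correlation with the block, leaving out experiment 2, pairwise experiments, an estimated correlation under the other settings, the conidial list without 1 gene, the z test on reads and the exact binomial test were chosen after the result was seen. The number of genes changed by methylprednisolone was 0 in edgeR and in all alternatives except 1 with the experiment as a block and 3 in DESeq2 with the block. At an unadjusted p under 0.05 it was 30 in edgeR, 16 in DESeq2 and 24 in limma voom, and with the block 294 in edgeR and 96 in DESeq2. The lists changed by methylprednisolone numbered 3, against 5 with library totals without TMM, without a filter, with the block and with log2(RPKM + 0.1), and 4 to 11 without 1 library. They were 0 with an estimated correlation, with fry, and with either and the block. The ribosomal median ranged from -0.056 (without treated library 2) to 0.38 without 1 library. That of tRNA synthetases and translation factors ranged from -0.076 (without treated library 2, and -0.076 without control 1) to 0.25. These fits had no block and left an experiment unpaired, so the ranges also hold differences between experiments. The conidial list was called without a filter (median 0.30, adjusted p = 0.00262) and without control 1 (median 0.12, adjusted p = 7.0e-04), with an adjusted p of 0.662 and 0.423 with an estimated correlation. Its median was negative in some other settings, for example -0.091 with library totals. Without the misplaced gene AFUA_1G01590 it was -0.065 against 0.0083 with it (adjusted p = 0.569), 0.19 without a filter (adjusted p = 0.0114) and 0.083 without control 1 (adjusted p = 0.00551). An estimated correlation called 0 lists in each of 14 settings. It also gave no call for ribosome biogenesis between experiments 2 and 1, so these 0 calls tell little. Genes differing between experiments numbered 2119, against 1385 in DESeq2, 761 to 2541 without 1 library, 340 without experiment 2 and 169 for experiment 3 minus 1. The authors' called genes were 902, against 9030 marked up or down, 8350 at an FDR of 0.05 without a fold limit, 12 in the z test on values divided back to reads, 8 in the exact binomial test and 911 to 1029 without 1 library. The cause of these differences was not tested, apart from fewer libraries where some were left out and the scale of the values in the z test. Of 83 named genes, 17 changed sign in at least 1 of 17 settings (26 of 1380 values). Of 458 tested list values, 355 kept the sign of the median, 407 their side of the threshold and 311 both.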

Other observations

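The gene clusters were lists fixed before the data were examined. What to describe of them, the limits used and the genes named in this part were chosen after the values were seen, and no hypothesis is offered. Over the 6 libraries tef1 was at 32005 ± 4580 CPM (SD, n = 6), the flavohemoprotein gene fhpA at 9804 ± 3997 CPM, the elongation factor EF-2 gene AFUA_2G13530 at 8514 ± 843 CPM and the glycolytic gene gpdA at 8146 ± 808 CPM. The gene fhpA ranged from 3529 to 13627 CPM.

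Many genes of secondary metabolite clusters had few reads over the 6 libraries, while single members of some clusters had many. The numbers of cluster genes given here count only members with reads, so members without any read are left out. All 7 fumigaclavine genes and all 4 helvolic acid genes had at most 10 reads each, as had 3 of 4 fumitremorgin genes, 5 of 8 gliotoxin genes, 4 of 6 DHN melanin genes and 10 of 15 fumagillin and pseurotin genes. The gliotoxin genes had 1779 reads in total, of which gliT had 1441, the fumagillin and pseurotin genes 2839, of which fpaI had 2314, and the DHN melanin genes 418, of which pksP had 393. All 4 galactosaminogalactan genes with reads, which serve an adhesive polysaccharide of the hyphal surface, were above 1 CPM, with 9900 reads in total.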
